A study of Escherichia coli with 9 samples.

How the data were processed

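Per the labels' protocols, cultures of an E. coli MG1655-derived strain were induced with 0.2% arabinose, grown to an OD600 of 0.6 and crosslinked with 0.5% formaldehyde, and FLAG-tagged proteins with their RNA were recovered on anti-FLAG beads. After reversal of the crosslinks an ERCC RNA spike-in was added, rRNA was depleted, and libraries of 200 to 300 bp fragments were amplified by 12 PCR cycles and sequenced as pairs of 150 bases. Spike-in values were not analysed here. The submitters' processing notes name fastp 0.20.0 and STAR 2.7.11b without giving their roles, and the design text names PEAKachu as the peak caller. Groups, replicates and batches were taken from the labels, which give each of 3 batches 1 library per group.

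There were 2 deposited tables, 1 per protein, each with the 3 immunoprecipitation libraries of that protein and the same 3 tag-control libraries. Replicates entered the authors' peak calling together, so a list has no replicates of its own. Per the file headers the library columns hold a signal per peak. These deposited values are read counts divided by 1 factor per library, since in each of the 12 columns 100% of the values became whole numbers within 0.0001 after multiplication by a recovered factor. Factors ran from 0.90 to 1.15 in the CsdA table and from 0.66 to 1.52 in the PNPase D492G table. Because the tables were scaled separately, tests between libraries stayed within a table. Of 8 permutation tests on listed peaks, 2 compared the widths and the deposited fold changes of the peaks of both lists, which describes the lists and not a difference between the proteins. The authors' log2 fold changes and their standard errors compare immunoprecipitation with tag control. A z score per peak in the deposited tables matches a 1-sided normal p-value, and the authors' deposited p-value and adjusted p are given per peak. Listed peaks have an adjusted p under 0.05 and at least a 2-fold change in the deposited tables. The ratio of adjusted to raw p gives 9177 regions tested for CsdA and 12847 for PNPase D492G. The last listed region has rank 1648 by p for CsdA and 1916 for PNPase D492G, so 49.2% and 83.0% of the regions up to that rank are listed. How the authors merged or split peaks is not given in the sources used here.

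The main test, chosen before the data were examined for tables of scaled values, was limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1), with no further scaling, no filter and no block, and Benjamini-Hochberg adjustment over the peaks of a table. A log2 difference on that scale understates the change of low peaks. Values are means ± SD of 3 libraries. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A floor covers that of the control reads alone. P-values measure the spread between libraries of separate batches. The labels give each library a batch, equal to its replicate number, and libraries were paired by it. Library names of the PNPase D492G group follow another numbering, so the pairing rests on the batch label alone. Deviations from the group means correlated within pairs at 0.18, 0.08 and 0.09 for CsdA and at -0.01, 0.00 and -0.05 for PNPase D492G, which gives no sign of pairing in the latter. DESeq2 1.42.0 and edgeR 4.0.16 were run as alternatives on the recovered reads with the authors' factors.

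On simulated data drawn from the levels of the real peaks, limma recovered 74% of 2-fold and 98% of 4-fold changes among 811 CsdA peaks, and 9% and 85% among 1590 PNPase D492G peaks, with 100 peaks changed per size. Of all calls, 2.8% and 2.1% were false. At 2-fold among the PNPase D492G peaks, edgeR recovered 24% and DESeq2 17%. These shares hold for that setting, where most peaks were unchanged.

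Overlaps of peaks were counted on the same strand with at least 1 base, and compared with 1000 circular shifts of at least 10000 bases over a length of 4636213 bases, the end of the last listed peak. Group medians were compared by 2-sided permutation tests with 100000 resamples. Loci were formed from 8-fold peaks less than 10000 bases apart in either table and on either strand, and bounded by the first and last of them.

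The rule for named items, written before the data were examined, asked for genes: the 10 with the highest authors' fold change with separated groups, the 5 with the highest level, 5 with peaks in both tables, 5 per table in 1 only, members of gene lists and check genes. No gene could be assigned, so it was applied to peaks, 1 per run of peaks less than 300 bases apart, and the parts on gene lists and check genes were void. That change, the runs and the loci were chosen after the data were seen. The peaks' coordinates refer to a chromosome sequence whose genome and annotation were not used here. A gene table of the MG1655 assembly ASM584v2 was on hand for names, but coordinates were not carried between sequences. Feature classes, positions along genes, gene lists and sequence composition of peaks were therefore not analysed.

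Alternatives were the batch block, other pseudocounts (0.5 and 5), TMM and median-ratio factors over the listed peaks, a mean of at least 10, the count models, stricter thresholds, other overlap rules and leaving out each library.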

Results

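The series asked which RNAs of Escherichia coli are crosslinked to CsdA, a DEAD-box RNA helicase, and to PNPase, the exoribonuclease polynucleotide phosphorylase, which was used as its D492G variant. Each protein was expressed with a FLAG tag from an arabinose-inducible pBAD plasmid in a strain lacking chromosomal PNPase and the helicases DbpA, RhlB, RhlE and SrmB. The same strain carried an RNase E truncated from residue 500 to residue 1061, the part on which the RNA degradosome, a complex that joins RNase E with PNPase, a helicase and other proteins, assembles. Cultures at 37 °C were treated with 0.5% formaldehyde for 10 min, and RNA recovered with anti-FLAG beads was sequenced. Control libraries came from the same strain expressing a FLAG-sp-HA tag. There were 9 libraries, 3 for each of FLAG-CsdA, FLAG-PNPase D492G and the tag control, and each batch held 1 library per group. Peaks are given by start and end on the single chromosome sequence of the deposited tables and by the strand written there. Whether that strand is that of the RNA or its complement was not established here. All peaks are marked intergenic in the tables without a feature name, and no annotation of that sequence was used, so no gene is assigned to any peak.

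Reads recovered from the scaled values summed, over the 811 CsdA peaks, to 1538494, 1309337 and 1127675 in FLAG-CsdA replicates 1 to 3, and to 490746, 469198 and 543781 in the tag controls. Over the 1590 PNPase D492G peaks they summed to 1670970, 1340291 and 1211362 in the FLAG-PNPase D492G libraries, against 204777, 206065 and 198104 in the same controls. These sums cover listed peaks and are not the depth of the libraries. Low peaks rest on few reads: the median tag-control mean was 32.1 scaled reads per CsdA peak and 15.3 per PNPase D492G peak.

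Relative to the tag control, RNA from 4 short stretches of the chromosome was higher with FLAG-CsdA by far more than at most other listed peaks. RNA before immunoprecipitation was not analysed here. For either protein, differences from the tag control may therefore include differences in RNA level between cultures. Of 27 peaks with a limma log2 difference of at least 3 over the tag control (8-fold), 24 (88.9%) lay in these stretches. The ends of a locus are its outermost 8-fold peaks, so weaker peaks beside it lie outside by construction. The plus-strand locus at 2885541 to 2889386 held 8 such peaks, with a median log2 difference of 4.62, and the next peak, at 2889675 to 2889949, had 2.77. The strongest, at 2889065 to 2889386, had 181 ± 16.3 scaled reads in FLAG-CsdA against 2.65 ± 0.82 in the control (SD, n = 3 each), a log2 difference of 5.66 (SE 0.26, limma adjusted p = 3.9e-09). Between 2530408 and 2541538, 9 CsdA peaks passed 8-fold. They included the plus-strand peak at 2538616 to 2538869 (192 ± 11.9 against 5.74 ± 1.31) and the much more abundant minus-strand peak at 2530408 to 2530818 (4856 ± 706 against 507 ± 35.0, log2 difference 3.25, SE 0.15). At 2082180 to 2083532 on the plus strand, 4 peaks passed, with a median of 4.04. The peak at 2083026 to 2083214 there had 106 ± 17.4 against 3.21 ± 2.84 scaled reads, and its log2 difference of 5.04 became 4.19 without tag control 1. In the minus-strand run at 1808857 to 1810321, 3 of 4 peaks passed and the lowest had 2.84. The first to pass, at 1809268 to 1809547, rose from 51.3 ± 6.83 to 1122 ± 39.4, a log2 difference of 4.43 (SE 0.16, limma adjusted p = 7.4e-10).

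Most other CsdA peaks showed modest enrichment. The authors' deposited table listed 811 CsdA peaks of 62 to 499 bases (median 301), 429 on the plus and 382 on the minus strand, covering 240587 bases. Their median log2 fold change in the authors' deposited table was 1.42 (quartiles 1.19 and 1.78), and 147 peaks (18.1%) reached 4-fold there. Peaks came in runs, defined as same-strand peaks with fewer than 300 bases between them. There were 498 runs, and 66 of them held at least 3 peaks and together 283 peaks (34.9%). Of those 66 runs, 12 had a median limma log2 difference of at least 2. A run of 9 peaks at 3260619 to 3263911 on the plus strand, picked after its values were seen, had a median limma log2 difference of 2.27 and overlapped no PNPase D492G peak. Its peak at 3263079 to 3263286 had 198 ± 13.3 scaled reads against 26.1 ± 8.17 (log2 difference 2.92, SE 0.23). Another CsdA peak with no PNPase D492G counterpart, at 510862 to 511155 on the minus strand, had 46.4 ± 6.73 against 6.16 ± 1.42.

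The 5 CsdA peaks named for the most reads had log2 differences of 1.04 to 1.60. At 4036631 to 4036954 on the minus strand FLAG-CsdA had 170781 ± 16081 scaled reads against 79659 ± 14149 in the control, a log2 difference of 1.11 (SE 0.19). Plus-strand peaks at 3468088 to 3468560 and 3441927 to 3442391 had 37898 ± 1453 against 18400 ± 184 and 32606 ± 4133 against 14215 ± 1199, with log2 differences of 1.04 and 1.19. The minus-strand peak at 236884 to 237081 had 31107 ± 6339 against 12761 ± 2022 (log2 difference 1.28), and the plus-strand peak at 68630 to 69109 had 20404 ± 3476 against 6685 ± 598 (1.60). All 5 differences depend on the scaling. With factors computed over the listed peaks the first 4 lay between -0.41 and -0.10. That at 68630 was 0.22 with TMM and 0.14 with median ratios, and none of the 5 was past the threshold.

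By limma on log2(value + 1), 810 of the 811 CsdA peaks were higher in FLAG-CsdA at an adjusted p under 0.05, and in 799 (98.5%) each FLAG-CsdA value lay above each control value, where chance gives 5%. The peaks were chosen by the authors on the same libraries, so the count describes agreement between libraries and is not independent evidence. Within batches 1, 2 and 3 the median log2 ratio was 1.44, 1.47 and 1.30, and 810, 809 and 809 peaks were higher. TMM factors computed over the listed peaks, which take the median peak as unchanged, left 76 peaks, and the median log2 difference went from 1.39 to 0.05.

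**Figure D1:**
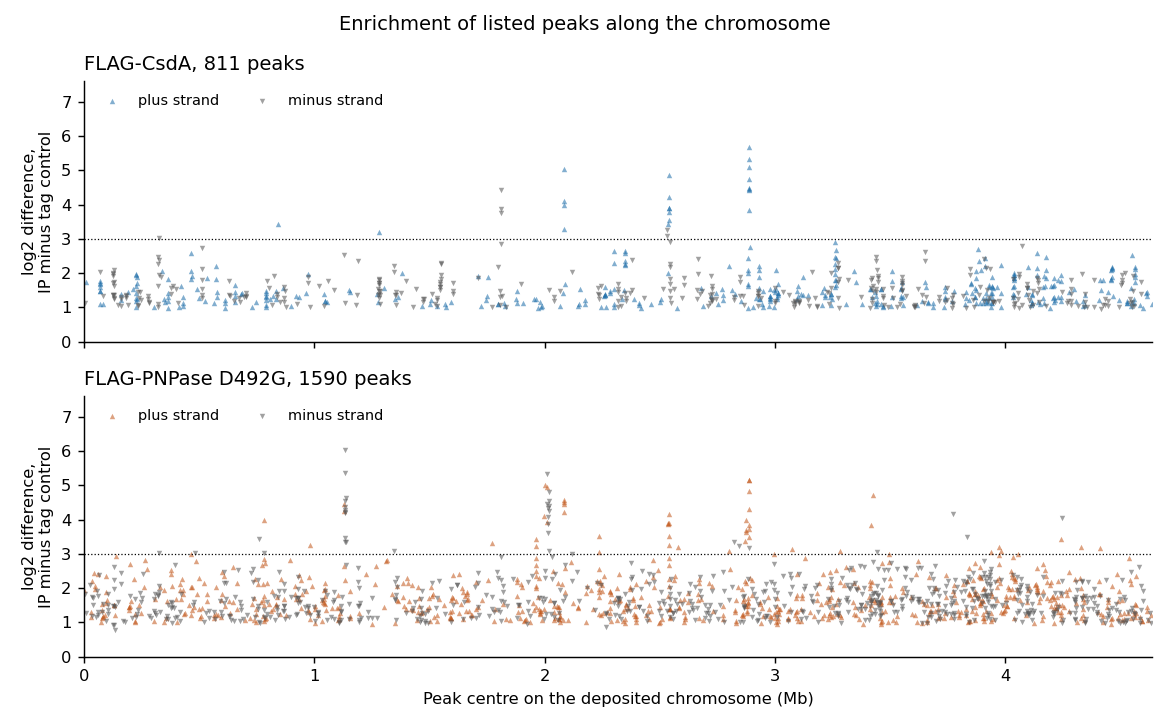
Limma log2 difference of immunoprecipitation minus tag control (vertical axis) for each listed peak against its centre on the deposited chromosome (horizontal axis, Mb), 811 FLAG-CsdA peaks above and 1590 FLAG-PNPase D492G peaks below, with triangles pointing up for the plus and down for the minus strand. The dotted line marks a log2 difference of 3, passed by 27 CsdA peaks, 24 of them in 4 narrow columns, and by 83 PNPase D492G peaks, 48 of them in columns of 3 or more.

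The PNPase D492G list was longer and held more strongly enriched peaks, a difference between lists of separate scaling that was not tested between libraries. Of 83 peaks at least 8-fold above the tag control by limma, 48 (57.8%) lay in 6 loci with 3 or more such peaks. On the scale of the authors' deposited table, which does not add 1 to the values, 143 peaks were at least 8-fold and 70 of them (49.0%) lay in loci formed in the same way. The locus with the highest single difference spanned 1129326 to 1137269, where 13 peaks passed 8-fold, 11 of them on the minus strand. The plus-strand run that enters it starts at 1128810, outside these ends, with its weakest peak at 2.64. Its minus-strand peak at 1131584 to 1131829 had 1020 ± 207 scaled reads against 14.5 ± 2.06 (SD, n = 3 each), a log2 difference of 6.03 (SE 0.24, limma adjusted p = 3.6e-07). At 2010497 to 2019434, 13 peaks passed, with a median of 4.34. Peaks there included 2011158 to 2011490 on the minus strand (223 ± 22.8 against 4.54 ± 0.23) and 2010497 to 2010865 on the plus strand (433 ± 174 against 12.4 ± 2.56). A further pair of 8-fold peaks lay at 1999002 to 1999663, of which 1999315 to 1999663 had 570 ± 169 against 16.5 ± 4.43 (log2 difference 5.02, SE 0.29). The plus-strand run at 2871048 to 2873992 had 4 of 7 peaks past 8-fold, the first at 2871453. The CsdA table listed no peak at 1999002, 2010497 or 2871453, and 2 peaks under 8-fold at 1129326. A region missing from a table either failed the authors' thresholds or was not tested, and the difference between the proteins was not tested.

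The authors' deposited table listed 1590 PNPase D492G peaks of 73 to 468 bases (median 261), 812 on the plus and 778 on the minus strand, covering 419457 bases. Their median log2 fold change in the authors' deposited table was 1.66 (quartiles 1.31 and 2.16), and 488 (30.7%) reached 4-fold. Runs of at least 3 peaks were rarer than for CsdA relative to the list, with 59 runs holding 230 peaks (14.5%), a difference not tested. At 14 peaks all 3 tag-control libraries were at 0. The minus-strand peak at 2822909 to 2823064 was at least 8.14-fold higher, that at 2886023 to 2886190 at least 5.93-fold and the plus-strand peak at 4057691 to 4057865 at least 5.43-fold, against a floor of 3 counts over the control group. Each peak rests on few reads (48, 35 and 32 over the 3 FLAG-PNPase D492G libraries), whose counting error the bounds leave out. The first rests on replicate 3 above all, without which its bound falls to 4.47-fold. The minus-strand peak at 3775295 to 3775434 rested on replicate 1, with 649 scaled reads there and 103 and 67.8 in replicates 2 and 3. Its log2 difference of 4.15 became 3.18 without replicate 1, and 2.63 with TMM factors over the listed peaks, no longer past the threshold (limma adjusted p = 0.12).

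Peaks with the most PNPase D492G reads were enriched 3.34-fold to 5.87-fold in means. The minus-strand peaks at 4164310 to 4164571 and 4033191 to 4033452 had 93857 ± 18373 and 93852 ± 18375 scaled reads against 18763 ± 4678 and 18162 ± 4466. Both have a width of 262 bases and near-equal values in each library, so their reads may be shared and the values of each are uncertain. At 4166217 to 4166536 the values were 86138 ± 15122 against 25822 ± 7908 (log2 difference 1.78, SE 0.32). The plus-strand peak at 2727277 to 2727579 had 84118 ± 14621 against 20377 ± 5993 (2.08, SE 0.31). With factors computed over the listed peaks, the log2 differences of the 5 peaks named for the most reads lay between 0.17 and 0.96, none past the threshold.

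By limma 1577 of the 1590 peaks were higher in FLAG-PNPase D492G at an adjusted p under 0.05, and in 1546 (97.2%) each of its values lay above each control value (chance 5%). As for CsdA, the list was chosen on these libraries. Within batches 1, 2 and 3 the median log2 ratio was 1.57, 1.58 and 1.57, with 1581, 1590 and 1572 peaks higher. TMM factors over the listed peaks left 66 peaks, with a median log2 difference of 0.09 in place of 1.59.

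Both proteins had at least 3 peaks past 8-fold at 3 loci, and 1 such peak each at another locus, 322592 to 322973 on the minus strand, with log2 differences of 3.04 for CsdA and 3.03 for PNPase D492G. At 2885541 to 2889386, 8 CsdA peaks and 8 PNPase D492G peaks (7 of the latter on the plus strand) passed 8-fold, with medians of 4.62 and 4.09 over these peaks. The minus-strand peak among them, at 2886023 to 2886190, had 0 in each control. It passed on the log2(value + 1) scale, and its log2 fold change in the authors' deposited table was 5.00. Its bound against the floor of 3 counts was lower, at 5.93-fold. The CsdA peak at 2887052 to 2887436 had 273 ± 45.3 against 9.31 ± 2.63 scaled reads, and the PNPase D492G peak at 2887040 to 2887410 had 344 ± 192 against 10.2 ± 4.29. At 2082180 to 2083532, 4 peaks passed in each table, with medians of 4.04 and 4.49. The PNPase D492G peak at 2082803 to 2083099 had 277 ± 136 against 10.3 ± 2.98. Between 2530408 and 2541538, 9 of 10 CsdA and 6 of 12 PNPase D492G peaks passed. Of these, 2 CsdA peaks lay on the minus strand, and all 6 PNPase D492G peaks on the plus strand. The overlapping peaks at 2539984 to 2540275 for CsdA and 2539789 to 2540085 for PNPase D492G had log2 differences of 3.91 (SE 0.22) and 4.16 (SE 0.37). In the minus-strand runs that start at 1808857 and 1808889, the 4 CsdA peaks had a limma median of 3.81 (lowest 2.84). The 4 PNPase D492G peaks, none 8-fold by limma, had a median of 1.93 (lowest 1.05). In the authors' deposited table the highest log2 fold change of these PNPase D492G peaks was 3.08, past 8-fold. The tables were scaled separately, so no library of one was tested against a library of the other.

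**Figure D2:**
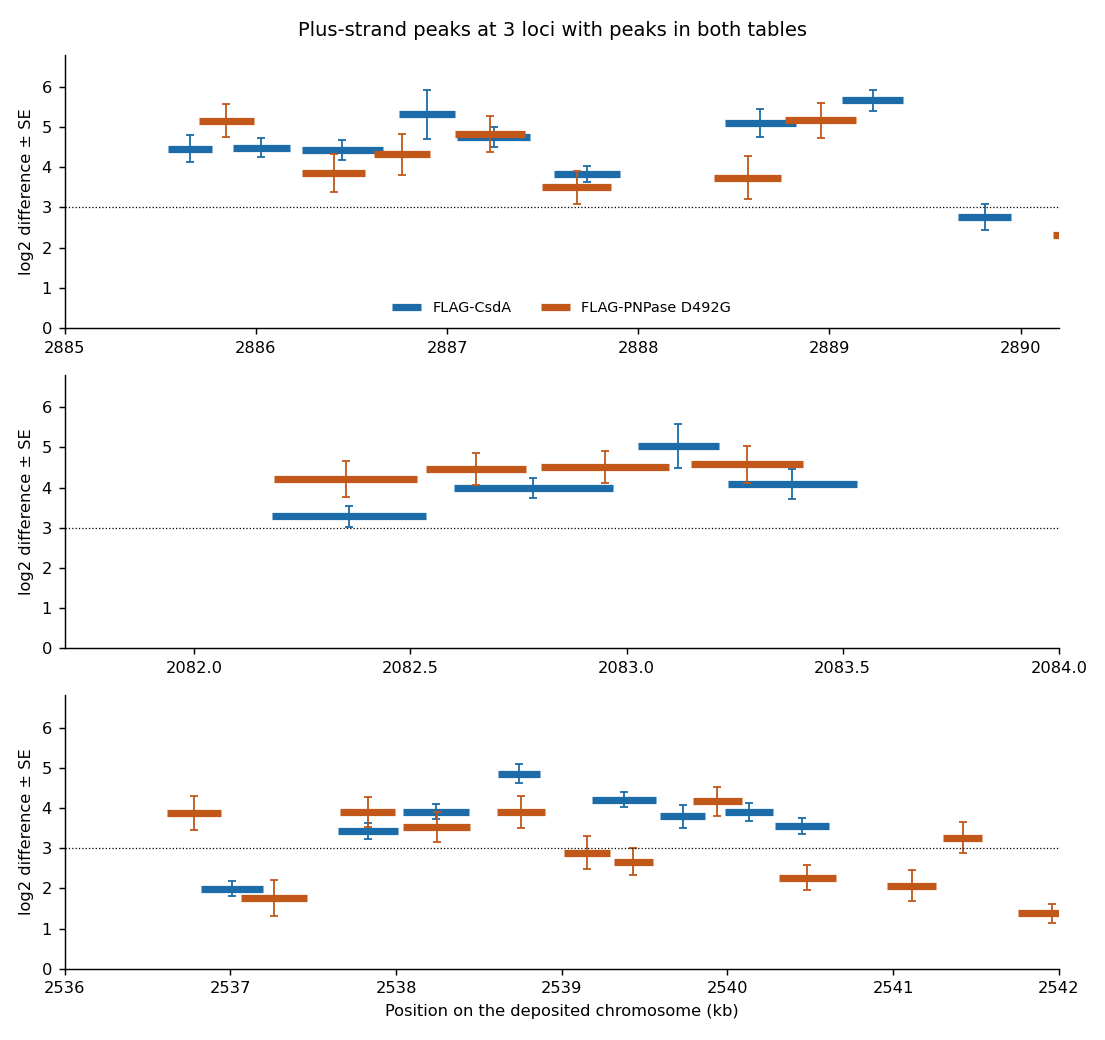
Plus-strand peaks at 3 loci with peaks in both tables, drawn to scale from start to end (horizontal axis, kb on the deposited chromosome) at the height of their limma log2 difference over the tag control, with vertical bars for ± 1 SE, FLAG-CsdA in blue and FLAG-PNPase D492G in orange. In the top panel the highest CsdA peak stands at 5.66 and the highest PNPase D492G peak at 5.16, and the dotted line marks 3.

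Replicates of FLAG-PNPase D492G spread more at some loci than at others. Over the 8-fold peaks at 2885541 to 2889386, the median log2 difference from the control mean was 5.01, 3.27 and 4.24 in replicates 1, 2 and 3 (SD 0.87), and at 2082180 it was 5.22, 3.60 and 4.67 (SD 0.82). At 2871453, where CsdA had no listed peak, they stood in the same order, at 4.13, 3.00 and 3.87 (SD 0.59). The same replicates stood at 3.99, 4.21 and 4.75 at 1129326 (SD 0.39) and at 4.22, 4.16 and 4.62 at 2010497 (SD 0.25). FLAG-CsdA replicates differed less, with SDs of 0.13 to 0.21 at its 4 loci.

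**Figure D3:**
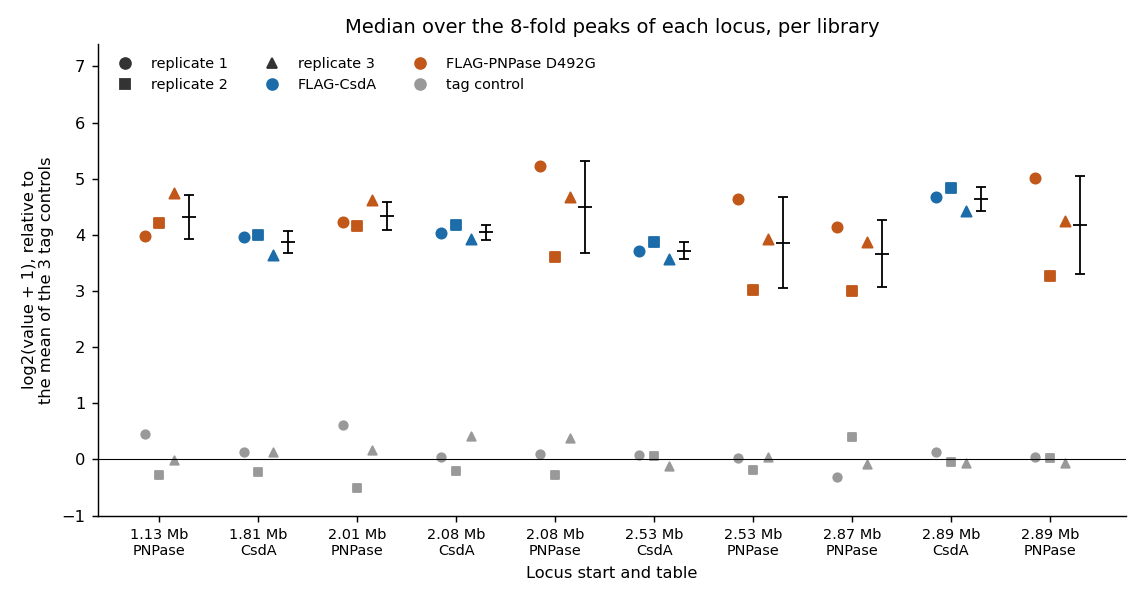
Median log2(value + 1) over the 8-fold peaks of each locus, relative to the mean of the 3 tag controls (vertical axis), for each library of the table named under each locus start (horizontal axis), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 immunoprecipitations. Replicate 1 of FLAG-PNPase D492G is the highest at 2.08, 2.53, 2.87 and 2.89 Mb and replicate 3 at 1.13 and 2.01 Mb, and tag controls lie between -0.51 and 0.61.

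The peak sets of the 2 proteins overlapped more than shifted sets did. A same-strand overlap of at least 1 base with a PNPase D492G peak was found for 281 of 811 CsdA peaks (34.6%, exact 95% interval 31.4 to 38.0). The interval treats peaks as independent, which neighbouring peaks of a run are not. Shifting 1 set around the chromosome 1000 times gave a mean of 71.8 and a maximum of 105 (1-sided permutation p = 0.001, the smallest these shifts can give). Shifted sets keep widths and spacing but not expression. In the other direction 285 of 1590 PNPase D492G peaks (17.9%) overlapped a CsdA peak. If the lists were independent, the 1590 of 12847 regions listed for PNPase D492G would give 100.4 overlapping CsdA peaks. Likewise the 811 of 9177 regions listed for CsdA would give 140.5 overlapping PNPase D492G peaks, against the 285 found. Both values assume that each list's peaks were among the regions tested for the other protein. Both lists used the same 3 control libraries. In 10 simulations of unchanged groups against those controls DESeq2 called no region in both, with at most 2 calls for either group. A call there took an adjusted p under 0.05 and a change above 2-fold. None of these figures isolates a shared effect, and part of the excess may come from the shared controls, which are too few to split. On opposite strands 75 CsdA peaks overlapped a PNPase D492G peak against 72.0 in shifted sets (1-sided permutation p = 0.41). Among runs of at least 3 peaks with a median limma log2 difference of at least 2, 11 of 12 CsdA runs and 8 of 18 PNPase D492G runs held an overlapping peak, against 29 of 66 and 31 of 59 over all runs of at least 3 peaks.

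CsdA peaks that overlapped a PNPase D492G peak had fewer reads and larger fold changes. In the authors' deposited table their median log2 fold change was 1.53 against 1.36 for the other 530 CsdA peaks, and the median log2 mean level 5.35 against 7.01 (both BH-adjusted permutation p = 2.7e-05, from the smallest p the permutations can give, over 8 tests). For PNPase D492G the fold changes of overlapping and other peaks in the authors' deposited table, 1.64 and 1.66, were not distinguished (adjusted permutation p = 0.60), while the overlapping peaks had more reads (median log2 level 5.78 against 4.83) and were wider (293 against 254 bases). These p-values treat neighbouring peaks as independent, which they are not.

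Across the 281 overlapping pairs, Spearman's rho between the log2 fold changes of the authors' deposited table was 0.50 (95% interval 0.41 to 0.59) and Pearson's r 0.74. Regions are not independent replicates, and the comparisons share controls: simulated unchanged groups gave a Pearson correlation of 0.51, to be set beside the r of 0.74. The covariance was 0.593 against a simulated 0.074 (highest of 1000 simulations 0.120), a difference of 0.519. The simulated pairs had no enrichment, while the observed pairs were listed for at least a 2-fold change. Any spread of enrichment among them adds to the observed covariance, so the difference does not isolate what shared controls leave. The median difference, PNPase D492G minus CsdA, was 0.07 in the authors' deposited table, with PNPase D492G higher in 161 of 281 pairs.

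**Figure D4:**
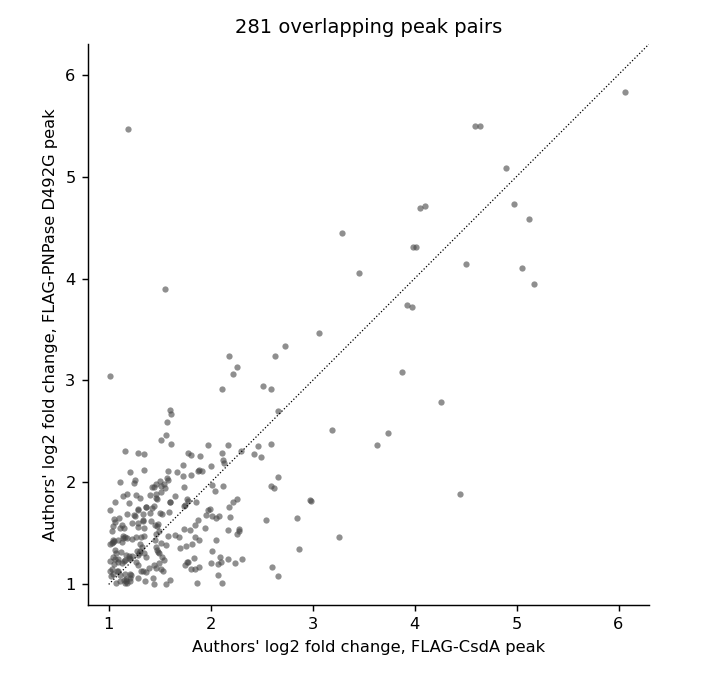
The 281 overlapping peak pairs, with the authors' deposited log2 fold change over the tag control for the CsdA peak (horizontal axis) and for the PNPase D492G peak (vertical axis), 1 point per pair and a dotted line of equal values. Pairs spread on both sides of the line, 161 above it, with Spearman's rho of 0.50 in the authors' deposited table.

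Peak density varied along the chromosome for both proteins. Per window of 500000 bases, CsdA had from 49 peaks (1000001 to 1500000) to 121 (3500001 to 4000000), and PNPase D492G from 131 (1500001 to 2000000) to 234 (3500001 to 4000000). The ratio of PNPase D492G to CsdA peaks per window, the last being shorter, ran from 1.38 to 2.78.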

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

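Alternatives added after the data were seen were edgeR, a doubled adjusted p, the fold beyond its error, a mean of at least 100, 8-fold on the authors' scale and counting repeat copies once. Factors over the listed peaks moved both counts: of 810 CsdA peaks TMM left 76 and median-ratio factors 69 (with 1 lower), and of 1577 PNPase D492G peaks each left 66. These factors set the typical listed peak to no change by construction. They also turned the log2 differences of 4 abundant CsdA peaks, at 4036631 (-0.27 with TMM, -0.34 with median ratios), 3468088 (-0.34, -0.41), 3441927 (-0.19, -0.26) and 236884 (-0.10, -0.18), with adjusted p from 0.11 to 0.86, and ended the calls of 10 further named peaks each. In the authors' deposited table of CsdA, 147 of 811 peaks had a fold of at least 4, 29 of at least 8, and 343 lay above 2-fold beyond their error. In the authors' deposited table of PNPase D492G, 1050 of 1590 peaks had an adjusted p under 0.01, 488 a fold of at least 4, 143 of at least 8, and 612 lay above 2-fold beyond their error. With the batch block, which pairs the libraries, limma called 810 CsdA and 1585 PNPase D492G peaks, and the block changed no call of a named peak. Leaving out 1 library gave 800 to 808 and 1534 to 1566 calls. DESeq2 and edgeR called 811 and 1590, all the listed peaks. That was likely beforehand, since the authors listed these peaks from the same libraries and the same factors were used. The overlap of 281 fell to 46 of 147 CsdA peaks with 4-fold peaks only (shifted mean 3.67) and to 143 with lists of equal length (shifted mean 35.8), both above each of 1000 shifts, and rho ran from 0.48 to 0.53. Not run, for want of an annotation or sequence of the build here, were the alternatives for feature class, position, gene lists and composition. Of simulated 2-fold changes at PNPase D492G peaks limma recovered 9%, DESeq2 17% and edgeR 24%; the cause of the low shares was not tested.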

Other observations

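The tests of scaling, of a single control library, of neighbouring peaks and of other groupings were chosen after the results they bear on had been seen; those of distant peaks within runs and of widths of near-equal peaks were written before. Some peaks of a table overlapped a stronger peak on the other strand. For CsdA there were 16 such pairs, in which the weaker peak held a median of 0.117% of the scaled reads of the stronger (0.024% to 38.6%) and had a log2 difference higher by a median of 0.47. For PNPase D492G there were 79 pairs, with a median share of 19.9% (0.115% to 97.7%; under 10% in 29 pairs) and a median log2 difference higher by 0.16 in the weaker peak (quartiles -0.17 and 0.47). Counts of opposite-strand overlap within a table, 28 CsdA and 148 PNPase D492G peaks, were near the means of shifted sets, 36.1 and 134 (1-sided permutation p = 0.87 and 0.14).

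Where both proteins were strongly enriched, the 3 control libraries are a first place to look, since both tables use them. Over the 39 peaks past 8-fold by limma at the 3 loci with at least 3 such peaks in each table, the lowest log2 difference after leaving out any 1 control was 3.00. A single low control library therefore does not account for these loci. The PNPase D492G peak at 2886023 to 2886190, among the 39, had 0 in each control, so leaving 1 out does not test it. The spread of FLAG-PNPase D492G at the same loci is not a scaling of replicate 1 as a whole either: over all listed peaks its median log2 deviation was -0.076, while at these loci it was at least 0.72. The order of replicates was the same at 2871453, which has no listed CsdA peak. It differed at 1129326 and 2010497, where replicate 3 was the highest. Whether the order goes with shared loci was not tested. Differences between the cultures in the level of these RNAs before immunoprecipitation, and binding by both proteins, both stay open, since RNA before immunoprecipitation was not analysed here. A hypothesis is that these RNAs vary between cultures, and total RNA of the same cultures would test it.

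Neighbouring peaks in a run resembled each other in enrichment. Their median absolute log2 difference was 0.21 for 313 CsdA pairs against 0.36 for shuffled peaks (permutation p = 0.0001, the smallest 10000 shuffles can give), and 0.39 for 328 PNPase D492G pairs against 0.49 (p = 0.0006). Reads spanning neighbouring peaks are a candidate source. Peaks of a run with at least 500 bases between them were no more alike than shuffled peaks, which was the outcome predicted for such reads. The values were 0.35 against 0.36 over 262 CsdA pairs (permutation p = 0.48) and 0.61 against 0.49 over 156 PNPase D492G pairs (permutation p = 0.96). The shuffles drew on all listed peaks and not only on those of runs, so the outcome does not single out such reads. Enrichment of whole transcripts stays open, because a p above the threshold does not show that distant peaks of a run are unrelated (52 and 43 runs gave such pairs).

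Some distant peaks had near-equal values in all 6 libraries of a table (within 0.1 on the log2 scale, at a mean of at least 100). CsdA had 7 peaks of 212 bases, 5 on the plus and 2 on the minus strand, with FLAG-CsdA means of 759 to 785 scaled reads, and 3 peaks of 312 bases with means of 450 to 456. Reads counted at each copy of a repeated sequence are a candidate explanation: 27 near-equal pairs had widths within 2 bases (of 2861 pairs), against 1 among 5766 pairs whose widths differed by 3 to 7 bases. The 27 pairs fall in 5 groups, 21 of them among the 7 peaks of 212 bases and 2 in the PNPase D492G table, so they are not independent. The MG1655 assembly ASM584v2 names 7 rrl and 7 rrs genes for ribosomal RNA, but the peaks were not matched to them. Counting repeat copies once left 281 overlapping CsdA peaks of 802. Copies were searched for only among peaks with a mean of at least 100, a level that 74 of 281 overlapping pairs reached in both tables. Whether the overlap of the proteins rests on copies at lower levels was therefore not tested.

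With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For each protein 1 split, the real one, gave as many calls by limma: 810 for CsdA and 1577 for PNPase D492G, with 0 as the highest of the others, including those that part all 3 pairs. The authors chose these peaks by the real grouping of the same libraries, so few calls in other splits were to be had in advance. The counts are therefore no evidence against a random grouping. At an unadjusted p under 0.05 the others gave 2 to 10 CsdA peaks and 6 to 31 PNPase D492G peaks. DESeq2 and edgeR were not run on the other splits.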
